A study of Homo sapiens with 12 samples.

How the data were processed

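Polyadenylated RNA of 786-O cells with restored BBOX1 or an empty vector was measured in 12 libraries, 3 each from BBOX1 cells, empty-vector cells, BBOX1 xenografts and empty-vector xenografts. Per the labels' protocols, libraries were made with an NEBNext Ultra kit, a type that does not mark strand, and sequenced as paired ends. Groups and replicate numbers were taken from the sample titles. The deposited table holds raw read counts per gene, whole numbers that the authors did not normalise. Per the submitters' processing notes the tools were fastp, STAR, featureCounts and DESeq2 and the build hg38; their versions and roles, the annotation release and any removal of mouse reads are not given in the sources used here. All 58735 gene identifiers and names of the table were identical to those of GENCODE release 29, whose GRCh38 coordinates, lengths and GC content were used.

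Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group with a minimum count of 10, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Cells and xenografts were fitted apart, each with its own spread between replicates. The test of the difference between settings used all 12 libraries, 4 group means and 1 shared spread. SE is the absolute log2 fold change divided by the square root of the F statistic. It is approximate, above all where a group is near 0 counts or the change is near 0. SD is the spread of CPM over 3 libraries. A test of each design on simulated counts with 200 changed genes recovered, in edgeR, 44%, 96%, 98% and 100% of genes changed by 1.2, 1.5, 2 and 4 times in cells (14753 genes, 7 false of 176 calls). In xenografts it recovered 2%, 36%, 86% and 98% (15844 genes, 14 false of 125 calls). In the difference between settings it recovered 0%, 22%, 72% and 96% (16647 genes, 6 of 101), and between empty-vector settings 8%, 84%, 100% and 100% (15588 genes, 12 of 158). Changed genes were drawn only from genes of higher mean count, so recovery at low counts was not measured. The simulated libraries of a comparison shared 1 spread per gene. In comparisons across settings the false calls therefore do not cover the unequal spread of cells and xenografts.

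Gene lists, 25 of pathways and 6 of cell type markers with 853 distinct genes, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over all lists of a comparison. Members that passed are counted after adjustment over all genes and adjusted over the list alone. Erythroid markers had 0 tested members in each comparison, and a list with fewer than 3 tested members has no camera test. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and a ratio with 1 to 3 counts has an exact binomial interval at 95%; both cover counting error only, since reads without molecular identifiers are not independent molecules. No list's median changed when members at 0 were set to this bound.

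The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names BBOX1, TBK1, MTOR and RPTOR in any case. For each BBOX1 comparison it takes, among protein-coding genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups in CPM, the 8 of largest rise and the 8 of largest fall by fitted log2 fold change. It takes 5 in each direction in the same way for the difference between settings and for the empty-vector comparison. From each list in each BBOX1 comparison within a setting it takes up to 3 members of smallest p past the threshold, where the list is called or has at least 3 such members, and from each marker list up to 3 members of highest CPM in xenografts. Of the genes the rule gives, the text prints a part, and some that it gives are not reported here; genes outside it are said to have been chosen after their values were seen. Alternatives were size factors of DESeq2, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 in place of edgeR, a fold of at least 2, the replicate number as a block, protein-coding genes alone, all 12 libraries in 1 fit, each library left out in turn, and for lists an estimated correlation and fry of limma. Leaving out genes of chromosome 14, and a correction of each library's log ratios for transcript length and GC content by natural splines with 4 degrees of freedom, were added after the data had been seen, as were a list of motile cilium genes and one of keratinocyte markers.

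Replicates were compared before use by a chi-square of their counts over genes. Per degree of freedom it was 1.92 to 2.82 among cell libraries of a group and 12.7 to 16.3 among empty-vector xenografts. Among BBOX1 xenografts it was 45.9 and 45.6 for replicate 1 against replicates 2 and 3, and 9.41 between those 2. No pair differed by less than sampling noise, so each library counts as 1 sample. The biological coefficient of variation was 3.33% in cells and 16.7% in xenografts, which limits xenografts to larger shifts. Mouse reads were not separated here.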

Results

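Polyadenylated RNA was sequenced from 786-O cells, an established human line of clear cell renal cell carcinoma. The cells carried a lentiviral vector that restored expression of BBOX1, the enzyme of the last step of carnitine synthesis, or an empty vector. Each kind of cell was grown in culture or as a xenograft in immunodeficient NSG mice, which gave 4 groups of 3 libraries. The series title frames the question: how BBOX1 relates to signalling by the kinase TBK1 and by mTORC1 in this carcinoma. Total counts per library were 26758712, 18272906 and 15627686 for cultured cells with BBOX1 and 16317539, 16357127 and 22067530 with the empty vector. They were 13729031, 15054113 and 16159837 for xenografts with BBOX1 and 15171681, 18937852 and 17968022 with the empty vector. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

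The restored gene was measured first, because it checks the labels. BBOX1 (ENSG00000129151) lies on the plus strand of chromosome 11 at 27040725 to 27127809 (GRCh38), and the antisense gene BBOX1-AS1 (27047186 to 27220113, minus strand) overlaps it, so reads counted without strand cannot be told apart between them. In cultured cells BBOX1 had 29085, 20202 and 16953 counts in the 3 BBOX1 libraries, or 1097, 1116 and 1093 CPM (counts scaled to the size of each library), and 0 counts in each of the 3 empty-vector libraries. Against a floor of 3 counts over the empty-vector group this was at least 19926-fold higher. In xenografts BBOX1 stood at 1263, 1300 and 1809 CPM with BBOX1 and at 0.651, 0.326 and 0.837 CPM with the empty vector, from 10, 6 and 14 counts. The log2 fold change in xenografts was 11.29 (SE 0.31, n = 3 per group, edgeR adjusted p = 1.46e-08). All 12 libraries therefore carried the BBOX1 level that their labels give.

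**Figure D1:**
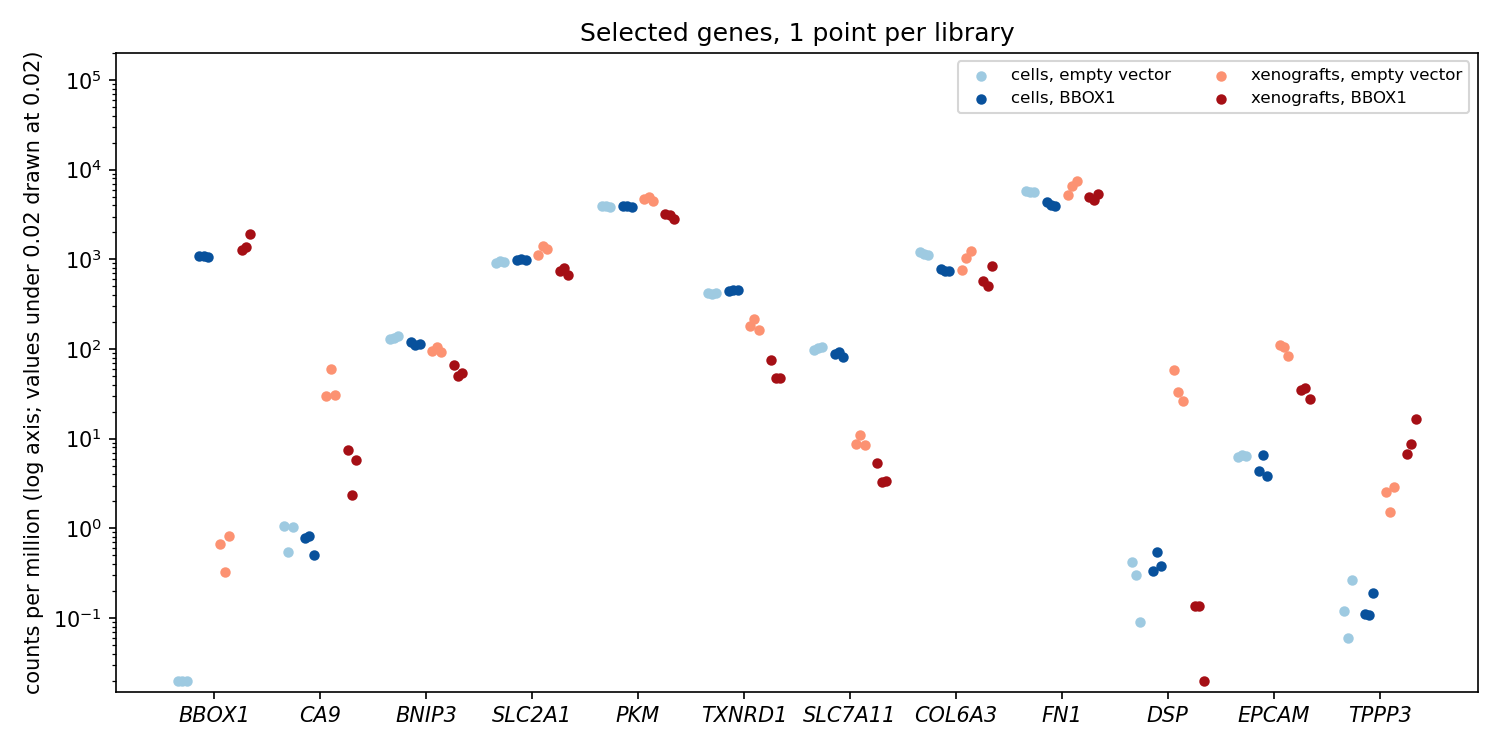
Expression of 12 genes in CPM on a log axis, with 1 point per library and 3 libraries in each of 4 groups; values under 0.02 are drawn at 0.02. BBOX1 separates the groups in both settings, COL6A3 and FN1 are lower with BBOX1 in cultured cells, and CA9, TXNRD1, DSP and EPCAM are lower with BBOX1 in xenografts.

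The first comparison asked what BBOX1 changed in cultured cells. Abundant transcripts of matrix genes were among those that fell: COL6A3, a chain of collagen VI, went from 1179 to 770 CPM (log2 -0.61, SE 0.02, n = 3 per group), and FN1, which encodes fibronectin, from 5784 to 4153 CPM (log2 -0.48, SE 0.02). The amino acid transporter subunits SLC7A5 and SLC3A2 rose by log2 0.37 (SE 0.02) and 0.28 (SE 0.03), and the interferon-inducible gene BST2 rose from 144 to 201 CPM (log2 0.49, SE 0.03). Of 77 transcripts of cytosolic ribosomal proteins 39 rose by small amounts and 38 did not pass; the call of the list was lost with an estimated correlation (limma camera adjusted p = 0.207). At an adjusted p under 0.05 in edgeR, 1276 of 14960 tested genes rose and 1176 fell, with a median fold of 1.14 among them, and 12 of the risen and 41 of the fallen genes changed at least 2-fold. When all 12 libraries were fitted together with 1 shared spread, 1 gene rose and 1 fell. The spread between replicates was small, with a biological coefficient of variation of 3.33%, and at this spread shifts of this size passed.

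Outside BBOX1 itself, the genes with the largest fold changes in culture were lowly expressed. The desmosomal plakophilin PKP2 rose from 1.87 to 3.75 CPM (log2 0.99, SE 0.21, edgeR adjusted p = 0.00095), DHX58, a regulator of RNA sensing, by log2 0.82 (SE 0.20), and the potassium channel gene KCNH2 by log2 0.76 (SE 0.18). PSD2, NPR1, TM4SF19 and KCNJ15 rose by log2 1.45, 1.15, 0.99 and 0.72. Among falls, the mucin gene MUC22 had 57 counts over the empty-vector group and 3 over the BBOX1 group, a ratio of 21.1 with a 95% counting interval of 6.85 to 105. PLD5 had a log2 of -2.09 (SE 0.50) and the retinol transporter gene STRA6 of -1.70 (SE 0.41). FOXQ1, PTCHD1 and LPAR4 had log2 values of -1.37, -1.41 and -1.34, all from about 1 CPM. RGPD5 (log2 -2.26) has near-identical copies and is uncertain. The calls of PSD2 (without BBOX1 replicate 3 or empty-vector replicate 3, adjusted p up to 0.0814) and of NPR1 and TM4SF19 (without BBOX1 replicate 1 or empty-vector replicate 1 or 3, up to 0.104 and 0.118) in edgeR rested on single libraries. So did those of KCNJ15 (without BBOX1 replicate 2 or empty-vector replicate 1 or 3, up to 0.109) and RGPD5 (without empty-vector replicate 3, 0.0720). The same holds for FOXQ1 (without BBOX1 replicate 2 or 3 or empty-vector replicate 1 or 2, up to 0.101), PTCHD1 (without BBOX1 replicate 3 or any empty-vector library, up to 0.131) and LPAR4 (without BBOX1 replicate 1 or 2 or empty-vector replicate 3, up to 0.204).

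Genes of the pathway in the series title moved little in culture. TBK1 (ENSG00000183735) had a log2 fold change of -0.00 (SE 0.07, edgeR adjusted p = 0.981) and MTOR (ENSG00000198793) of -0.02 (SE 0.03, adjusted p = 0.753). RPTOR (ENSG00000141564), which encodes the mTORC1 scaffold raptor, rose by log2 0.17 (SE 0.05, edgeR adjusted p = 0.0128), a call lost without BBOX1 replicate 1 or empty-vector replicate 2 or 3 (adjusted p up to 0.144). Among 36 genes of mTORC1 and its nutrient-sensing regulators, 5 rose and 2 fell (6 and 2 when adjusted over the list alone), including the activating GTPase RHEB at log2 0.17, the Rag GTPase RRAGA at -0.21 and the mTORC1 inhibitor AKT1S1 at 0.16. The list as a set was not called (limma camera adjusted p = 0.537), with a median of 0.02 and a mean of -0.02. Of 20 genes of the TBK1 module, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.537). The autophagy receptor SQSTM1 rose by log2 0.23 and TRAF2 by 0.19, and TAX1BP1 fell by 0.11, a call lost without BBOX1 replicate 1 or 3 or empty-vector replicate 3 (edgeR adjusted p up to 0.157). These data measure transcripts and not kinase activity.

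Of 27 fixed lists with enough tested members, 10 were called in culture by limma camera with a preset correlation of 0.01, 7 of them up and 3 down. With a correlation estimated from these libraries 0 were called (5 at an unadjusted p under 0.05, and 16 adjusted by fry). Of 77 ribosomal protein genes 39 rose and 0 fell (43 and 2 when adjusted over the list alone; camera adjusted p = 1.24e-18, and adjusted p = 0.207 with an estimated correlation), among them RPL30 at log2 0.20 (SE 0.03), RPL13A at 0.18 and RPL35A at 0.18. Of 33 ribosome biogenesis and MYC target genes 13 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 1.05e-06, and 0.0724 with an estimated correlation), including the spermidine synthase SRM at 0.23 and RRP12 at 0.20. Of 46 proliferation genes 14 rose and 3 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.000132, and 0.164 with an estimated correlation), with the replicative helicase subunit MCM7 at 0.19 and the S-phase regulator E2F1 at 0.22. Of 54 nuclear genes of oxidative phosphorylation 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00102, and 0.207 with an estimated correlation), with CYC1 at 0.17 and COX5B at 0.22.

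Other lists called up in culture held p53 targets, lysosomal genes and genes of cholesterol synthesis. The cell cycle inhibitor CDKN1A rose by log2 0.41 (SE 0.03), PHLDA3 by 0.30 and the death effector BAX by 0.31, among 6 of 22 p53 targets that rose and 0 that fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00136, and 0.207 with an estimated correlation). The lysosomal saposin precursor PSAP rose by 0.21 and the membrane protein LAMP1 by 0.19, among 9 of 37 lysosome and autophagy genes that rose and 2 that fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00136, and 0.164 with an estimated correlation). The sterol sensor INSIG1 rose by 0.22 among 4 of 26 cholesterol synthesis genes that rose and 0 that fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.027, and 0.229 with an estimated correlation). The list call was lost without BBOX1 replicate 2 or without empty-vector replicate 3 (camera adjusted p = 0.078 each).

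Lists called down in culture were led by the extracellular matrix genes, of which 16 of 38 fell and 4 rose (17 and 5 adjusted over the list alone; limma camera adjusted p = 2.45e-05, and 0.0724 with an estimated correlation). TNC, which encodes the matrix protein tenascin C, fell by 0.55 on the log2 scale (SE 0.03), beside COL6A3 and FN1. Of 15 epithelial junction and keratin genes 5 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0261, and 0.207 with an estimated correlation). The cadherin CDH6 had a log2 of -0.31, KRT19 of -0.23 and the claudin CLDN4 of 0.36. That list call was lost without BBOX1 replicate 1 (camera adjusted p = 0.051). Of 13 mitochondrially encoded mRNAs 2 fell and 1 rose, as when adjusted over the list alone (camera adjusted p = 0.027, and 0.714 with an estimated correlation). This call was lost without BBOX1 replicate 3 (camera adjusted p = 0.0528) and without empty-vector replicate 3 (adjusted p = 0.563), where the direction also turned. In culture, longer genes tended to have lower log2 fold changes (Spearman rho across 9327 genes -0.30, and 0.37 with GC content, genes not being independent replicates). After a correction for both, chosen after the data had been seen, the median of the matrix list moved from -0.07 to -0.04 (95% interval -0.10 to 0.01) and that of the ribosomal protein list from 0.09 to 0.06 (0.04 to 0.07).

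Further fixed lists were not called as sets by limma camera in culture, although single members changed. By fry 16 lists were called in culture, some of these among them. Among 28 targets of the hypoxia-inducible factors 7 rose and 5 fell (9 and 8 adjusted over the list alone; limma camera adjusted p = 0.843), with the angiogenic factor VEGFA at log2 -0.22, STC2 at -0.37 and TGFA at 0.22. Their median was 0.01 and their mean -0.02. Among 40 ATF4 targets 9 rose and 9 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.843). Interferon-response genes gave 7 risen and 1 fallen of 38, also over the list alone (camera adjusted p = 0.0529), NF-kappaB genes 6 and 5 of 25 (10 and 7; 0.999), glycolysis genes 6 and 2 of 25 (6 and 2; 0.126) and NRF2 targets 4 and 4 of 25 (4 and 4; 0.843). Risen and fallen counts were 3 and 3 of 26 for the unfolded protein response (4 and 3 over the list alone; camera adjusted p = 0.284), 3 and 2 of 18 for MHC class I (4 and 3; 0.66) and 4 and 3 of 23 for fatty acid synthesis (6 and 4; 0.747). They were 3 and 0 of 22 for fatty acid oxidation (6 and 1 over the list alone; camera adjusted p = 0.252), 1 and 2 of 14 for proximal tubule genes (1 and 2; 0.659) and 3 and 2 of 26 for immediate early genes (3 and 2; 0.999). Of 10 tested genes of carnitine synthesis and transport 0 passed in edgeR, also when adjusted over the list alone (1 at an unadjusted p under 0.05, 0 in DESeq2; camera adjusted p = 0.843). For NF-kappaB genes the median was -0.12 and the mean -0.01 while camera pointed up. Medians and means also differed in sign for ATF4 targets (0.00 and -0.03), NRF2 targets (0.05 and -0.03), fatty acid synthesis (0.03 and -0.01) and immediate early genes (0.01 and -0.01).

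The second comparison asked what BBOX1 changed in xenografts, where shifts were larger and fewer genes passed. CA9, a carbonic anhydrase induced by hypoxia, fell from 39.5 to 5.14 CPM (log2 -2.94, SE 0.37, n = 3 per group), and the lipid droplet gene PLIN2 from 557 to 283 CPM (log2 -0.98, SE 0.13). TXNRD1, a thioredoxin reductase, fell from 183 to 56.3 CPM (log2 -1.70, SE 0.19), and the epithelial adhesion gene EPCAM from 98.2 to 32.9 CPM (log2 -1.58, SE 0.15). At an adjusted p under 0.05 in edgeR, 308 of 16126 tested genes rose and 586 fell, with a median fold of 1.82 among them, and 85 and 284 of these changed at least 2-fold. DESeq2 gave 731 and 1002, no filter on low counts 797 and 1408, the replicate block 103 and 352, and a fit of all 12 libraries 1563 and 2105. The counts also depended on single libraries. Without BBOX1 replicate 1, which stood apart from the other 2 libraries of its group, 1854 genes rose and 2447 fell, and without BBOX1 replicate 2 or 3 the counts were 105 and 292 or 27 and 153. Without empty-vector replicate 1, 2 or 3 they were 115 and 306, 22 and 172, or 47 and 308.

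Apart from BBOX1, the named genes with the largest changes in xenografts were those that fell. The desmosomal gene DSP fell from 38.5 to 0.0903 CPM (log2 -8.65, SE 0.52, edgeR adjusted p = 8.98e-06). The glutamine transporter SLC38A3 fell by 6.21 on the log2 scale (SE 0.51). Over the BBOX1 group there were 0 counts of EMX1 and CRTAM, against 87 and 64 over the empty-vector group, at least 25.0-fold and at least 18.4-fold lower. ST8SIA2 had 1 count against 357 (ratio 308, 95% counting interval 54.9 to 12203) and TMEM176A 2 against 563 (ratio 243, interval 66.9 to 2011). Higher with BBOX1 were TMEM236 (log2 4.04, SE 0.71), C1orf194 (2.66, SE 0.38), TPPP3 (2.21, SE 0.36), CFAP99 (2.13), VWA3A (2.11) and the axonemal dynein gene DNALI1 (2.00). The edgeR calls of TMEM236 and VWA3A were lost without BBOX1 replicate 3 or empty-vector replicate 2 or 3 (adjusted p up to 0.0647 and 0.0958). Those of CFAP99 and DNALI1 were lost without any 1 library other than BBOX1 replicate 1 (adjusted p up to 0.187 and 0.126).

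In xenografts TBK1 had a log2 fold change of 0.19 (SE 0.14, edgeR adjusted p = 0.423), MTOR of 0.06 (SE 0.13, adjusted p = 0.813) and RPTOR of -0.15 (SE 0.18, adjusted p = 0.634). In edgeR 0 of 35 mTORC1 genes passed, also when adjusted over the list alone (5 at an unadjusted p under 0.05, 1 higher and 1 lower in DESeq2; limma camera adjusted p = 0.833). Of 20 TBK1 module genes 0 rose and 1 fell, also over the list alone (camera adjusted p = 0.235). That gene was the adaptor AZI2 at log2 -0.76, named after its value was seen, and its edgeR call was lost without any 1 library other than BBOX1 replicate 1 (adjusted p up to 0.135).

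Of 28 fixed lists with enough tested members in xenografts, 11 were called down and 2 up by limma camera, and 0 with an estimated correlation (5 at an unadjusted p under 0.05, and 6 adjusted by fry). Of 46 proliferation genes 9 fell and 0 rose (29 and 0 adjusted over the list alone; camera adjusted p = 1.81e-12, and 0.521 with an estimated correlation), with the mitotic cyclin CCNB2 at log2 -0.78 (SE 0.14) and the mitotic kinases AURKA at -0.68 and PLK1 at -0.69. Of 40 ATF4 targets 13 fell and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 1.11e-08, and 0.181 with an estimated correlation), with the mitochondrial PEP carboxykinase PCK2 at -0.97 (SE 0.12), the transcription factor CEBPB at -0.78 and the serine enzyme SHMT2 at -0.78. Of 32 targets of the hypoxia-inducible factors 9 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 7.81e-07, and 0.181 with an estimated correlation), with CA9, PLIN2 and the mitophagy receptor BNIP3 at -0.78 (SE 0.13). Of 25 glycolysis genes 8 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 3.23e-06, and 0.181 with an estimated correlation). The glucose transporter SLC2A1 went from 1256 to 725 CPM (log2 -0.79, SE 0.14), the pyruvate kinase PKM from 4621 to 3021 CPM (-0.61, SE 0.14) and the lactate exporter SLC16A3 from 621 to 441 CPM. The edgeR calls of BNIP3, SLC2A1, CCNB2 and SHMT2 were lost without BBOX1 replicate 3 or empty-vector replicate 2 (adjusted p up to 0.0679, 0.0847, 0.0874 and 0.0647), and that of AURKA also without empty-vector replicate 3 (up to 0.113). That of PLK1 was lost without BBOX1 replicate 2 or 3 or empty-vector replicate 2 or 3 (up to 0.113), and those of PKM and SLC16A3 without any 1 library other than BBOX1 replicate 1 (edgeR adjusted p up to 0.184 and 0.196).

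Of 26 NRF2 antioxidant targets 4 fell and 0 rose (8 and 0 adjusted over the list alone; limma camera adjusted p = 0.000103, and 0.181 with an estimated correlation), with TXNRD1, the haem oxygenase HMOX1 at log2 -1.12 and the cystine transporter SLC7A11 at -1.23. HMOX1 lost its edgeR call without BBOX1 replicate 3 (adjusted p = 0.0535), and SLC7A11 without BBOX1 replicate 2 or 3 or empty-vector replicate 2 or 3 (up to 0.116). Of 77 ribosomal protein genes 5 fell and 0 rose, also over the list alone (camera adjusted p = 3.23e-06, and 0.558 with an estimated correlation). RPS29 on chromosome 14 was at -0.72, lost without BBOX1 replicate 3 or empty-vector replicate 2 (edgeR adjusted p up to 0.0646). RPS12 was at -0.54 and RPL23A at -0.50, both lost without any 1 library other than BBOX1 replicate 1 (up to 0.128 and 0.168). Of 18 MHC class I genes 2 fell, also over the list alone (camera adjusted p = 6.51e-05, and 0.181 with an estimated correlation). These were the peptidase ERAP2 at -0.70, lost without BBOX1 replicate 2 or 3 or empty-vector replicate 2 or 3 (edgeR adjusted p up to 0.127), and HLA-C at -0.53, lost without any 1 library other than BBOX1 replicate 1 (up to 0.199). Of 26 genes of the unfolded protein response 2 fell (4 adjusted over the list alone; camera adjusted p = 0.00104, and 0.558 with an estimated correlation). These were MANF at -0.65, lost without BBOX1 replicate 3 or empty-vector replicate 2 or 3 (edgeR adjusted p up to 0.140), and PDIA6 at -0.74, lost without any 1 library other than BBOX1 replicate 1 (up to 0.176).

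Of 18 proximal tubule genes 5 fell (6 adjusted over the list alone), with the brush border peptidase ANPEP at -1.82 (SE 0.19), a list called at camera adjusted p = 0.0181 (0.558 with an estimated correlation) and lost without BBOX1 replicate 2 (0.0605) or empty-vector replicate 1 (0.0807). Of 38 matrix genes 3 fell, also over the list alone, with the proteoglycan LUM at -3.00 (SE 0.43), a list called at camera adjusted p = 0.03 (0.558 with an estimated correlation) and lost without empty-vector replicate 2 (0.0543) or 3 (0.311). Among 54 oxidative phosphorylation genes 0 passed in edgeR, also over the list alone (11 at an unadjusted p under 0.05, 0 higher and 2 lower in DESeq2; camera adjusted p = 0.02, and 0.602 with an estimated correlation). The list call was lost without BBOX1 replicate 1 (0.542) or empty-vector replicate 3 (0.166).

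Lists called up in xenografts were mitochondrially encoded mRNAs and p53 targets. Among 13 mitochondrially encoded mRNAs, with a median log2 of 0.48, 0 passed singly in edgeR, also over the list alone (6 at an unadjusted p under 0.05, 1 higher in DESeq2; limma camera adjusted p = 0.00104, and 0.558 with an estimated correlation). The share of counts from the mitochondrial chromosome was 7.96%, 12.56% and 13.7% in BBOX1 xenografts and 8.99%, 6.78% and 7.81% in empty-vector xenografts, so it was not raised in BBOX1 replicate 1. Of 22 p53 targets 2 rose and 0 fell, also over the list alone: TP53INP1 at log2 0.80 (SE 0.14) and SPATA18 at 1.00 (SE 0.21). That list was called at camera adjusted p = 0.0112 (0.521 with an estimated correlation) and lost without empty-vector replicate 1 (0.0535). TP53INP1 lost its edgeR call without BBOX1 replicate 3 or empty-vector replicate 2 or 3 (adjusted p up to 0.0627), and SPATA18 without BBOX1 replicate 2 or 3 or empty-vector replicate 1 or 2 (up to 0.14).

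The remaining lists were not called by limma camera in xenografts. Lysosome and autophagy genes gave 0 risen and 3 fallen of 37 (2 and 3 adjusted over the list alone; limma camera adjusted p = 0.051). Ribosome biogenesis genes gave 0 of 33 in either direction in edgeR, also over the list alone (4 at an unadjusted p under 0.05, 0 in DESeq2; camera adjusted p = 0.16). Epithelial junction genes gave 2 risen and 2 fallen of 20 (3 and 4 over the list alone; camera adjusted p = 0.962), with a median of 0.06 and a mean of -0.46. DSP and EPCAM pulled the mean down. The keratin KRT7 had a log2 of 1.68 (SE 0.37), a call lost without BBOX1 replicate 3 or empty-vector replicate 2 or 3 (edgeR adjusted p up to 0.148). Of 42 interferon-response genes 1 rose, TRIM22 at log2 0.70 (1 over the list alone; camera adjusted p = 0.0628), and of 32 NF-kappaB genes 1 rose and 1 fell (2 and 1; 0.571). Cholesterol synthesis genes gave 0 of 25 in edgeR, also over the list alone (5 at an unadjusted p under 0.05, 1 higher in DESeq2; camera adjusted p = 0.0628). Fatty acid synthesis genes gave 0 risen and 1 fallen of 23 (1 and 6 over the list alone; camera adjusted p = 0.0628). Fatty acid oxidation genes gave 0 of 23 in edgeR, also over the list alone (3 at an unadjusted p under 0.05, 0 in DESeq2; camera adjusted p = 0.581). Fatty acid oxidation had a median of 0.03 and a mean of -0.05, with camera pointing down. Of 10 genes of carnitine synthesis and transport 2 rose and 0 fell, also over the list alone (camera adjusted p = 0.16): the acyltransferases CROT at log2 0.57 and CPT1B at 0.93. Of 26 immediate early genes 0 rose and 1 fell, the phosphatase DUSP5 at log2 -0.99, also over the list alone (camera adjusted p = 0.16). TRIM22, CROT, CPT1B and DUSP5 were named after their values were seen. Their edgeR calls were lost without BBOX1 replicate 2 or 3 or empty-vector replicate 2. Those of TRIM22 and CPT1B were also lost without empty-vector replicate 3, and those of CROT and CPT1B without empty-vector replicate 1 (edgeR adjusted p up to 0.116, 0.190, 0.188 and 0.122).

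**Figure D2:**
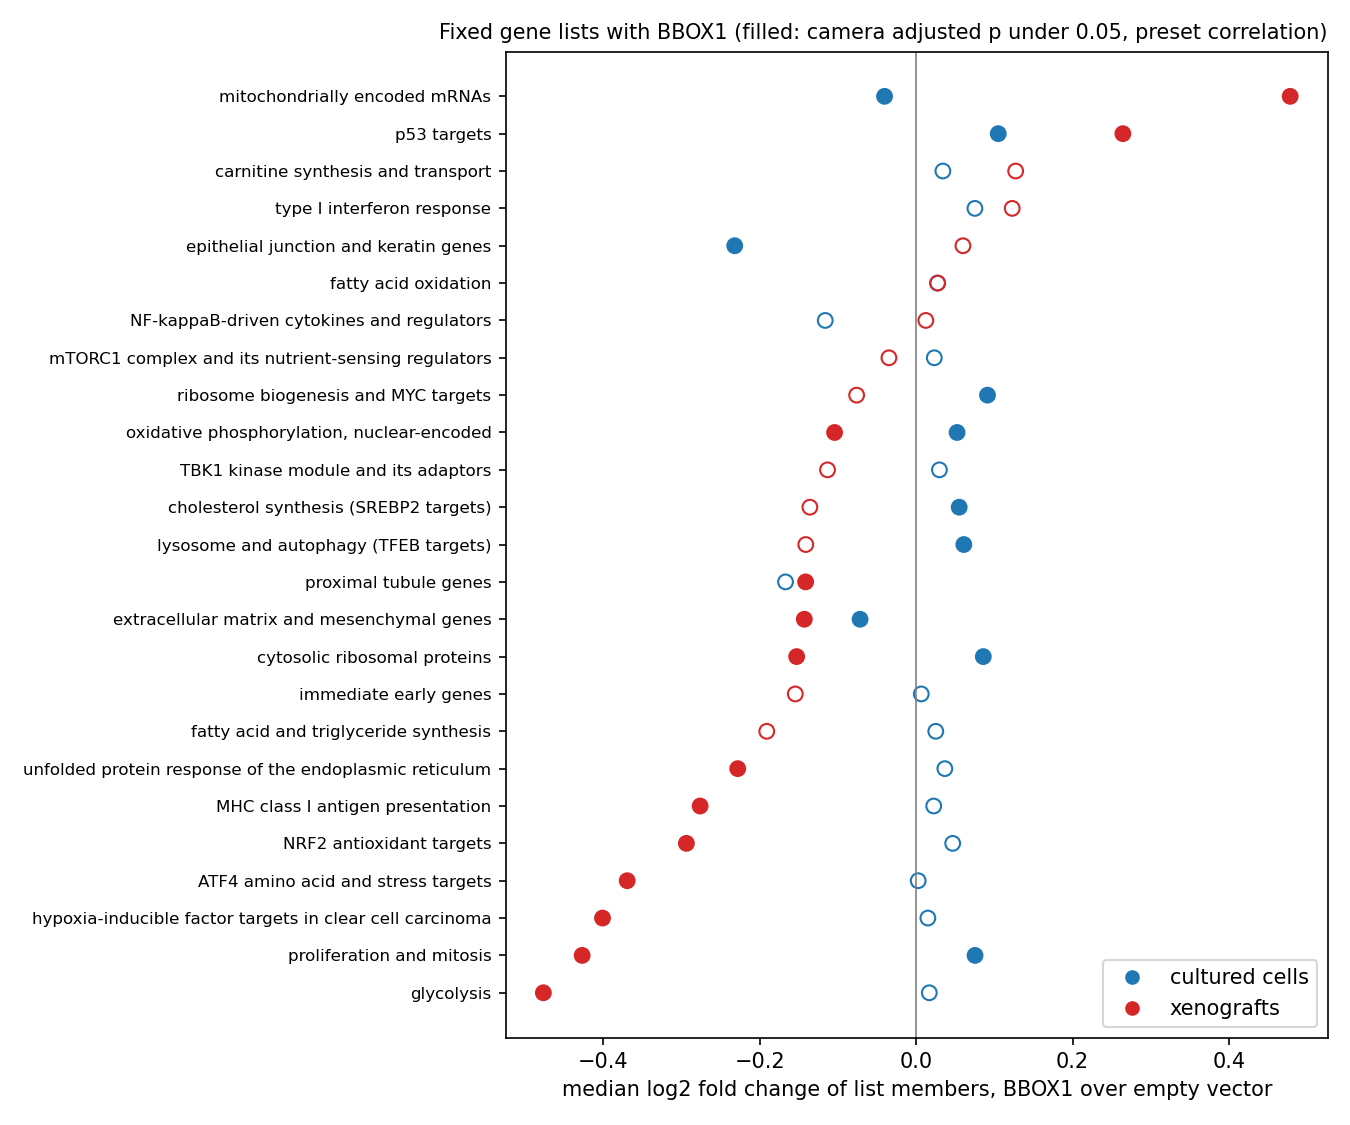
Median log2 fold change of the tested members of 25 fixed pathway lists, BBOX1 over empty vector, in cultured cells and in xenografts; a filled point marks a list called by camera with the preset correlation. Glycolysis (-0.48), proliferation (-0.43), hypoxia-inducible factor targets (-0.40) and ATF4 targets (-0.37) lie lowest in xenografts, while their medians in cells lie between 0.00 and 0.08.

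The third comparison asked whether the effect of BBOX1 differed between xenografts and cells, by a test of the difference itself in all 12 libraries. In edgeR it was higher in xenografts for 326 of 16927 genes and lower for 552. This fit gave all 12 libraries 1 shared spread, with a biological coefficient of variation of 11.9%. Fitted apart, cells had 3.33% and xenografts 16.7%. The gene counts and list calls below therefore rest on a spread that is not that of either setting. Glycolysis genes had a median difference of -0.47 on the log2 scale, with 9 of 25 members lower in the difference and 0 higher (14 and 0 adjusted over the list alone; limma camera adjusted p = 7.57e-09, and 0.0354 with an estimated correlation). ATF4 targets had a median of -0.37, with 14 of 40 lower and 0 higher (21 and 1 over the list alone; camera adjusted p = 2.43e-10, and 0.0376 with an estimated correlation). NRF2 targets had a median of -0.40 (camera adjusted p = 3.23e-05, and 0.0307 with an estimated correlation) and MHC class I genes of -0.31 (4.82e-06, and 0.0376). These were the 4 lists, of 14 called, that held with an estimated correlation. Proliferation genes, at -0.47, did not (camera adjusted p = 2.09e-18, and 0.172 with an estimated correlation). The count of 878 genes was 280, 280 and 324 without BBOX1 cell replicate 1, 2 or 3, 293, 301 and 287 without empty-vector cell replicate 1, 2 or 3. It was 4182, 804 and 536 without BBOX1 xenograft replicate 1, 2 or 3, and 1199, 358 and 648 without empty-vector xenograft replicate 1, 2 or 3. The differences of TBK1, MTOR and RPTOR were 0.19, 0.07 and -0.32 (edgeR adjusted p = 0.487, 0.792 and 0.364).

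Log2 fold changes in cells and in xenografts were weakly correlated across the 14371 genes tested in both, BBOX1 left out (Pearson r 0.0802, Spearman rho 0.0664). Genes are not independent replicates. Over genes called in at least 1 setting r was 0.162. Without BBOX1 cell replicate 1 or 3 it was 0.0471 or 0.0522, without BBOX1 xenograft replicate 1 or 2 it was 0.123 or 0.0455, and without empty-vector xenograft replicate 1 it was 0.0496. The same sign was seen in 51.8% of genes. ANPEP (log2 -0.52 in cells and -1.82 in xenografts) is an example of a gene that fell in both settings. Genes that fell in both numbered 111, against 38.1 from independent lists (Fisher's exact test, both tails, p = 9.0e-26). Those that rose in both numbered 21, against 23.7 (Fisher's exact test, both tails, p = 0.664). The cell and xenograft comparisons share no library, but both set BBOX1 cells against empty-vector cells. A standing difference between these cells other than BBOX1 would enter both comparisons. It cannot be told apart here from an effect of BBOX1. Without genes of chromosome 14 the number lower in both was 78, against 29.2 from independent lists.

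The last comparison set empty-vector xenografts against empty-vector cells, to show what the growth setting changed without BBOX1. Targets of the hypoxia-inducible factors were higher in xenografts for 25 of 32 genes and lower for 4 (also over the list alone; limma camera adjusted p = 7.12e-07, and 0.29 with an estimated correlation), with a median log2 of 2.24. All but 1 of the 46 proliferation genes were lower, 45 in edgeR over all genes and 46 over the list alone (camera adjusted p = 7.15e-15, and 0.29 with an estimated correlation). NF-kappaB genes (28 of 32 higher, 2 lower; camera adjusted p = 4.64e-08, and 0.29 with an estimated correlation), interferon-response genes (33 of 42 higher, 3 lower; 1.46e-06, and 0.355) and proximal tubule genes (16 of 18 higher, 0 lower; 1.97e-05, and 0.29) were higher in xenografts. Cholesterol synthesis genes (3 of 26 higher, 20 lower; camera adjusted p = 6.53e-06, and 0.351 with an estimated correlation) and ribosome biogenesis genes (0 of 33 higher, 28 lower; 4.27e-08, and 0.29) were lower. In edgeR 5650 of 15914 genes were higher in xenografts and 5273 lower, 2889 and 1569 of them at least 2-fold.

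Single genes with the largest changes between settings ended at 0 or near 0 counts in 1 of them. HHLA2, SLC38A3 and MAL had 0 counts over the empty-vector cells and were at least 537-fold, 398-fold and 372-fold higher in empty-vector xenografts. COL3A1, a fibrillar collagen, had 1 count in cells against 5847 in xenografts (ratio 6146, 95% counting interval 1103 to 242802). ATOH8, LCP1 and SLAMF7 had 0 counts over the empty-vector xenografts and were at least 182-fold, 57.1-fold and 45.0-fold lower there, and TEX15 had 1 count against 524 (ratio 498, interval 89.1 to 19726). Of 19 lists called by limma camera 13 were up and 6 down, and 0 were called with an estimated correlation (4 at an unadjusted p under 0.05, and 25 adjusted by fry).

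Markers of other cell types were followed because mouse host RNA can enter a xenograft library. Fibroblast and pericyte markers were higher in empty-vector xenografts than in cells for 7 of 8 genes and lower for 1 (limma camera adjusted p = 0.0121, and 0.29 with an estimated correlation). COL1A1 stood at 190 CPM (SD 88.0) in empty-vector and 233 CPM (SD 70.8) in BBOX1 xenografts, against 6.92 in empty-vector cells, and COL3A1 at 115 and 80.2 CPM. Their usual partners COL1A2 and DCN stayed at 0.141 and 0 CPM in empty-vector xenografts. The myeloid marker CD74 stood at 85.3 and 65.4 CPM, and EGFL7 led the endothelial markers at 4.24 and 4.44 CPM, below its 17.0 CPM in empty-vector cells. Among erythroid markers the highest, ALAS2, stood at 0.577 CPM in empty-vector and 0.0647 CPM in BBOX1 xenografts. Summed adipocyte markers stood between 5.86 and 10.9 CPM in xenografts and summed muscle markers at no more than 4.78 CPM. With BBOX1 in xenografts the fibroblast list was not called (0 of 7 rose and 1 fell, LUM, or 2 over the list alone; camera adjusted p = 0.575). The myeloid and adipocyte lists were not called by camera either, though fry called the myeloid list down (adjusted p = 0.00661; each 0 of 3 in edgeR and in DESeq2, 1 at an unadjusted p under 0.05; camera adjusted p = 0.21 and 0.566).

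Genes of chromosome 14 were lower with BBOX1 in both settings, a chromosome picked out only after the values were seen. In cultured cells the median log2 fold change of its 308 genes with at least 8 CPM was -0.17, or -0.19 relative to the other autosomes (95% interval of the median -0.19 to -0.17), and in edgeR 150 of them fell and 2 rose. In xenografts the median was -0.38, or -0.34 relative to the other autosomes (interval -0.36 to -0.28), with 64 fallen and 1 risen. HIF1A, on this chromosome, fell by 0.58 on the log2 scale in cells and by 1.53 in xenografts, more than the chromosome's median in each setting. It too was chosen after its values were seen. Its edgeR call in xenografts was lost without any 1 library other than BBOX1 replicate 1 (adjusted p up to 0.153). A link between its fall and the targets of the hypoxia-inducible factors was not tested. PCK2 and RPS29 are on chromosome 14 as well.

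**Figure D3:**
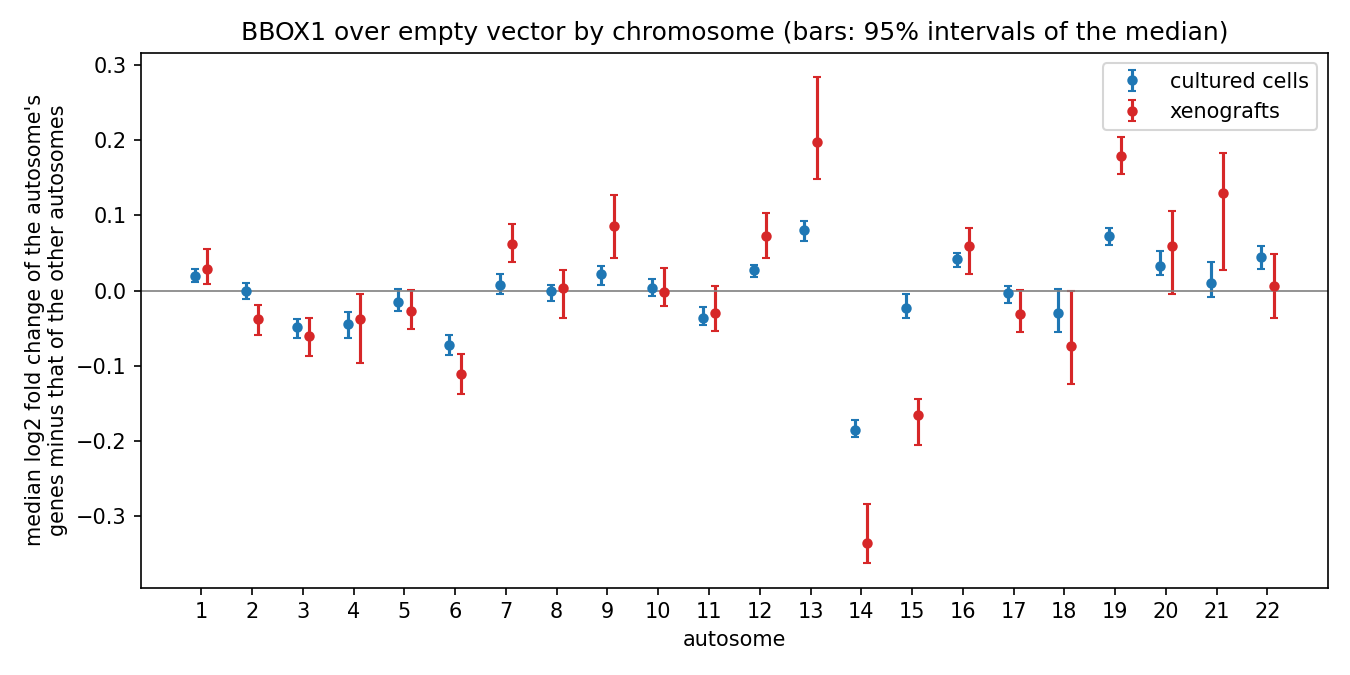
Median log2 fold change of the genes of each autosome, BBOX1 over empty vector, minus that of the other autosomes, with 95% intervals of the median as bars. Chromosome 14 lies lowest in cultured cells (-0.19) and in xenografts (-0.34), and chromosomes 13 (0.08 and 0.20) and 19 (0.07 and 0.18) lie above 0 in both.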

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

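The tests of keratinocyte and other host cells, of a difference already present in culture and of the splits of cultured cells were chosen only after the result was seen; the other splits were set out before. The effect of BBOX1 differed between xenografts and cells for 878 genes in edgeR at an adjusted p under 0.05, which is why these results are listed here. That fit gave cells and xenografts 1 shared spread, although the spread was larger in xenografts. The count moved to 280, 280 and 324 without BBOX1 cell replicate 1, 2 or 3, to 293, 301 and 287 without empty-vector cell replicate 1, 2 or 3, to 4182, 804 and 536 without BBOX1 xenograft replicate 1, 2 or 3, and to 1199, 358 and 648 without empty-vector xenograft replicate 1, 2 or 3. The largest positive differences among named genes were fitted at log2 6.00 for TP53AIP1, 5.78 for GRM8, 4.94 for TMEM236, 4.51 for SLC22A2 and 4.20 for FSIP2. The largest negative ones were -9.56 for SLC38A3, -9.35 for DSP, -9.06 for ST8SIA2, -8.11 for EMX1 and -7.36 for CRTAM. Fitted values of genes near 0 counts in a group depend on the prior count and are no bounds, and of these 10 genes DSP alone kept its call without each of the 12 libraries in turn.

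By limma camera the difference was negative for proliferation genes (adjusted p = 2.09e-18), ribosomal protein genes (1.98e-12), ATF4 targets (2.43e-10), glycolysis (7.57e-09), targets of the hypoxia-inducible factors (8.98e-07), MHC class I genes (4.82e-06), NRF2 targets (3.23e-05), the unfolded protein response (7.01e-05), lysosome and autophagy genes (0.000134), nuclear genes of oxidative phosphorylation (0.000255), ribosome biogenesis (0.000721), cholesterol synthesis (0.00884) and fatty acid synthesis (0.0348). It was positive for mitochondrially encoded mRNAs (0.000364). With an estimated correlation the call held for ATF4 targets (adjusted p = 0.0376), glycolysis (0.0354), MHC class I genes (0.0376) and NRF2 targets (0.0307). The call of cholesterol synthesis was lost without empty-vector xenograft replicate 3 (camera adjusted p = 0.0581), and that of fatty acid synthesis without BBOX1 cell replicate 2 (0.0592), BBOX1 xenograft replicate 2 (0.171) or empty-vector xenograft replicate 3 (0.0853).

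Of 100 drawn splits of the 12 libraries within their settings, 1, the real one, gave as many as 878 genes, and the highest other gave 730. This share under 0.05 argues against chance only for the case that BBOX1 has no effect in either setting. Such splits do not test an equal effect in both. The split that keeps both real groupings and swaps only the labels of the cells was not among those drawn. The 9 other splits that kept the real grouping of xenografts gave 415 to 730 genes and the 90 that broke it at most 40. For cells, xenografts and the empty-vector comparison 10 splits each are too few for a share under 0.05; 1 of 10, the real one, gave as many genes, with 2452, 894 and 10923 genes in edgeR against a highest other of 0 in each.

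A pattern within this difference is that 133 genes were at least 4 times lower in BBOX1 than in empty-vector xenografts. Of these, 120 were higher and 4 lower in empty-vector xenografts than in empty-vector cells, though the same empty-vector xenografts enter both comparisons. Mouse stroma, blood or muscle cells were examined by the summed markers of the 6 lists. The ratio of empty-vector to BBOX1 xenografts was 1.07, in a sum where fibroblast markers weigh most. Myeloid sums were higher with the empty vector by less than 4 times (99.9, 83.6 and 86.6 against 76.6, 61.2 and 69.6 CPM). Erythroid sums were higher by more (0.521, 0.434 and 0.837 against 0.136, 0.0649 and 0.0610 CPM) but under 1 CPM, with HBB and HBA1 at 0 CPM in both groups. Since LYZ, TYROBP and C1QB were also at 0 CPM in all xenografts, these counts may not register mouse cells. The markers therefore cannot decide on such a source, and the fibroblast marker LUM is itself among the 133 genes. Of keratinocyte transcripts, KRT5 and KRT14 together averaged 0.130 CPM and KRT1 and LOR were at 0 CPM in empty-vector xenografts. The same limit applies to mouse keratinocytes, so a source in such cells stays open. The summed list exceeded the limit first set (102, 116 and 120 CPM against 96.4, 107 and 107 in BBOX1 xenografts), but cultured cells reached 111 to 129 CPM. KRT17 (log2 -1.76) and SFN (-1.36), named after their values were seen, fell with BBOX1. Only 50 of the 133 genes were tested in culture. For these, a difference of this size already present there is argued against by a median of -0.21 (95% interval -0.32 to -0.04). The interval lies below 0 and reaches past the bound of -0.3 first set, and 9 genes were lower and 0 higher. The remaining genes did not pass the count filter in culture, so for them this test cannot decide. An effect of BBOX1 in the tumour setting, a difference in the cells that grew out in each group and host cells may each contribute. They were not tested apart.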

How the results depend on the processing

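The tests without chromosome 14 genes and with the length and GC correction were chosen only after the result was seen. Asking for a 2-fold change left 12 genes higher and 41 lower with BBOX1 in cells, 85 and 284 in xenografts, 248 for the difference between settings, and 2889 and 1569 between empty-vector settings. Fitting all 12 libraries together gave 1 and 1 gene in cells and 1563 and 2105 in xenografts. DESeq2 gave 731 and 1002 in xenografts and 1693 for the difference, no filter 797 and 1408, and 1662, and the replicate block 103 and 352, and 548. With an estimated correlation 0 lists were called in cells, 0 in xenografts and 4 for the difference, and fry called 16 in cells and 6 in xenografts. The correlation between settings was 0.162 over genes called in at least 1 setting. Apart from lost samples, the cause was not tested.

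Leaving out 1 library at a time gave 956 to 1180 genes higher and 873 to 1011 lower in cells, 22 to 1854 and 153 to 2447 in xenografts, 280 to 4182 for the difference, 5277 to 5725 and 4897 to 5483 between empty-vector settings, and correlations of 0.0455 to 0.123. Lists called were 8 to 11 in cells, 12 to 17 in xenografts and 13 to 15 for the difference. Log2 values of BBOX1 were 17.25 to 17.42 in cells, where they depend on the prior count, and 10.96 to 11.59 in xenografts. TBK1 in cells ranged from -0.0397 to 0.0546, its sign turning without BBOX1 replicate 3 (0.0546) and empty-vector replicate 3 (0.0421) and after the length and GC correction (0.0271), which also turned MTOR in cells (0.0180). In xenografts MTOR ranged from -0.0632 to 0.156, turning without BBOX1 replicate 1 (-0.0632) and empty-vector replicate 1 (-0.0103), and RPTOR from -0.29 to 0.12, turning without empty-vector replicate 3 (0.12). The difference for MTOR ranged from -0.0641 to 0.174, turning without BBOX1 xenograft replicate 1 (-0.0641). Mitochondrially encoded mRNAs in cells had camera adjusted p from 0.000118 to 0.563, turning without empty-vector replicate 3 (0.563). The cause was not tested.

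Of the genes called in cells DESeq2 shared 1844 of 2452, and of those in xenografts 879 of 894, while the replicate block shared 434 of 894. Replicate numbers showed no clear pairing of the libraries. Deviations from group means correlated at 0.04, 0.03 and 0.01 between cells of the same number, against at most -0.01, 0.01 and 0.003 between other numbers. Between xenografts of the same number they correlated at -0.16, -0.15 and 0.04, against at most 0.23, 0.11 and 0.11. A weak pairing in cells is thus not excluded. At the depth and replicate spread of each setting, edgeR recovered 2% of simulated 1.2-fold changes in genes of higher mean count in xenografts and 44% in cells. The biological coefficient of variation was 16.7% in xenografts and 3.33% in cells. The simulation gave all xenografts 1 spread per gene, so it does not represent a library that stands apart, such as BBOX1 replicate 1.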

Other observations

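The test of motile cilium genes was set out before its result but prompted by genes seen to rise, which were left out of the list; the tests of chromosome 14 were chosen only after the result was seen. In BBOX1 xenografts 7 of 57 motile cilium genes rose and 0 fell in edgeR, with a median log2 of 0.45 (limma camera adjusted p = 6.28e-07, and 0.388 with an estimated correlation; 7.67e-08 to 7.66e-05 without each library in turn). In cells 0 of 43 passed (camera adjusted p = 0.544), and the difference between settings was called (1.72e-05, and 0.149 with an estimated correlation). A gain of ciliary transcripts with BBOX1 in xenografts may be a hypothesis to test, which these libraries alone do not settle. Keratinocyte markers gave 0 risen and 2 fallen of 6 in xenografts (camera adjusted p = 0.156) and 1 risen and 0 fallen of 4 in cells (0.617).

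Chromosome 14 genes were lower with BBOX1 in both settings. Gene length or GC bias as the whole cause is argued against, since the median relative to other autosomes in cells stayed at -0.16 (95% interval -0.18 to -0.15) after the correction, and a few strongly regulated genes are argued against by 93.2% of its 308 genes having a negative log2 fold change there. All 16 windows of 10 Mb, 8 in each setting, had a median below 0, as a lower dose of the whole chromosome in the BBOX1 cells would give. With 93.2% of genes negative in cells and 88.0% in xenografts this was nearly fixed in advance and adds no separate support for a lower dose. Relative to other autosomes the shift was -0.19 in cells and -0.34 in xenografts. Other autosomes also shifted in both settings, such as chromosome 6 (-0.07 and -0.11) and chromosome 13 (0.08 and 0.20). Per library the relative level was -0.09, -0.08 and -0.10 in BBOX1 cells against 0.08, 0.08 and 0.09 in empty-vector cells. It was 0.00, -0.25 and -0.22 in BBOX1 xenografts against 0.20, 0.23 and 0.06 in empty-vector xenografts, so BBOX1 replicate 1 lay close to empty-vector replicate 3, which a uniform lower dose in BBOX1 xenografts leaves unexplained. An effect of BBOX1 on these genes was not tested apart from such a dose, since DNA was not analysed here.

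The matrix list was lower and the ribosomal protein list higher with BBOX1 in cells, where fold changes also followed gene length and GC content. The length and GC correction was added after the data had been seen, while the bounds of both tests were set out before their results. For ribosomal protein genes the median after correction was 0.0578 (95% interval 0.0403 to 0.0747; camera adjusted p = 1.35e-10), which argues against length and GC as the whole cause of the shift in the median. Before correction the list was called by fry (adjusted p = 0.0179) and not by camera with an estimated correlation (adjusted p = 0.207). For matrix genes the median after correction was -0.0380 (interval -0.10 to 0.01, camera adjusted p = 4.17e-06), short of the -0.05 set beforehand and also taken against 0. In cells the corrected median of expressed genes outside chromosome 14 was itself 0.02, so bounds taken against 0 depend on the zero point. The interval of the ribosomal protein list lay above 0.02. After correction the matrix list kept its camera call with the preset correlation, with 15 members lower and 6 higher. The median alone therefore does not decide between length and GC bias and an effect of BBOX1, and the call did not vanish with the correction. Before correction the matrix list, too, was not called by camera with an estimated correlation.

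Among the 133 genes at least 4 times lower in BBOX1 xenografts, abundant examples, chosen after their values were seen, are MAP3K4 (276 to 32.2 CPM, from empty vector to BBOX1), ANKRD50 (217 to 22.7), HNF4G (154 to 12.6) and FAM126B (139 to 10.2). Each kept its edgeR call without each of the 6 libraries in turn.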
